A study of Rattus norvegicus with 4 samples.

How the data were processed

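Total RNA from 4 cultures of NRK-52E, a rat kidney tubular epithelial cell line, was measured on 1-colour (Cy3) Agilent arrays, 1 array per dose of hydrogen peroxide (H2O2). Per the labels, confluent cells were exposed for 1 h to 0, 0.003, 0.006 or 0.009% H2O2, washed, and kept for 12 h without serum before extraction with a column kit. The 4 arrays lay on 1 slide, were read in 1 scan, and were placed in the order of the dose, so slide position and dose cannot be told apart. The amounts of RNA labelled and of spike-in added to each culture's RNA are not given in the sources used here.

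The authors read the slides with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09, array design 014879). Per the file headers, the spot signal is a linear intensity after the scanner software's background subtraction and detrending, with an error estimate in the same intensity unit, and carries no scaling between arrays. The deposited value table holds a linear ratio: in 100% of probes each value equalled the mean processed signal of the probe's spots divided by the median of the array's noncontrol spots, to within 1e-06 of the value. The medians of its columns were 0.962, 0.955, 0.965 and 0.972 from the control to the highest dose. That table is therefore close to array median scaling, and differs in how repeated spots are averaged and in keeping outlier spots. It was used as an alternative, not as the main values.

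Spots marked as non-uniform or as population outliers were left out, and the log2 signals of a probe's remaining spots were averaged. This mean was reduced by the log2 of the array's 75th percentile over noncontrol spots. Of 41012 probes, 41007 were used. Gene names came from the RefSeq accessions of the probes, looked up in a table of rat RefSeq genes on the GRCr8 assembly, used for names only. The array was annotated on an older assembly (rn4), so no positions are given. This named 10834 probes (26.4%) and 8963 genes. Other probes (Ensembl transcripts, predicted genes, expressed sequence tags and cluster consensus sequences) were kept without a name, and each probe or gene is called a feature. A gene with several probes took its brightest probe among those well above background on at least 1 array. The near-identical genes Hspa1a and Hspa1b cannot be separated by hybridisation.

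A comparison of 2 arrays used features well above background on at least 1 of them. Where the other side was not well above background, it was set to the higher of its own value and that array's lowest signal well above background, and the difference was taken as a bound, written as "at least". The error of a difference is the scanner software's spot error, propagated over the spots of both arrays. It covers the measurement of a spot only and not the spread between cultures, and its median was 0.21 on the log2 scale. With 1 array per dose there was no replicate check, no p-value was computed for a single dose against the control, and the number of arrays limits the precision of every value. A difference of at least 2-fold is a rule of size and not a test.

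A straight-line trend over dose was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 4 arrays, 2 residual degrees of freedom, Benjamini-Hochberg threshold 0.05). Its residual holds the spread of single arrays and any departure from a straight line. Under the 12 distinct orders of the arrays the count at an unadjusted p under 0.05 was also taken.

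Before the data were examined, 30 gene lists were fixed: NRF2 targets, other antioxidant enzymes, p53 targets, the integrated stress response, endoplasmic reticulum (ER) chaperones and the unfolded protein response, heat shock proteins, immediate early genes, inflammatory cytokines and NF-kB targets, secreted growth factors, WNT and hedgehog ligands, prostaglandin synthesis and receptors, damage-associated molecules, apoptosis and necroptosis, DNA replication, mitosis, DNA repair, cholesterol synthesis, glycolysis and hypoxia response, oxidative phosphorylation, cytosolic ribosomal proteins, metal handling, interferon response, tubule injury markers, proximal tubule function, epithelial junctions and keratins, YAP and TGF-beta targets, lysosome and autophagy, and markers of fibroblasts, endothelium and macrophages. The median log2 difference of a list's measured genes was placed among 10000 random lists of the same size drawn from 20 bins of mean signal, and lists with at least 5 measured genes were judged against the central 95%. This describes a pair of arrays and is not a test across samples.

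The genes named in the text were also chosen by a rule fixed at that time. They are the 8 highest and the 8 lowest genes with a gene symbol and well above background on both arrays at each dose, the 10 steepest called by the trend in each direction (none was called), the 4 members of each list with the largest absolute difference at 0.009%, bounds included (a few of these are not reported), and 10 genes always named: Hmox1, Nqo1, Cdkn1a, Atf3, Ddit3, Ptgs2, Hbegf, Mki67, Gapdh and Actb. Mki67 had no named probe.

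The alternatives were quantile normalization, array median scaling, scaling on 8 probes of the E1A spike-in RNA, normexp background correction (limma, offset 50), the deposited table, the mean of a gene's probes, features well above background on every array compared, and no filter or floor. Normexp had been planned on the mean pixel intensity of a spot, a column that the files used here do not hold, and was run on the median pixel intensity instead. The trend was repeated without each array, with a signal-dependent prior, and with the control against the 3 treated arrays as a group. A comparison of 0.009% with 0.003%, the alternatives for neighbouring doses other than quantile normalization and the deposited table, and the scalings tried for features chosen at 0.003% or 0.009%, were added after the data had been seen.

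The steps were tested on simulated data. With 50 genes at each size, simulated changes of 1, 2, 4 and 8 over the dose range (log2) were called by the trend in 0, 28, 88 and 98% of cases with spot error alone, and exceeded 2-fold in 46, 96, 100 and 100%, while 799 unchanged features passed 2-fold. With a departure of each array from the line (standard deviation 0.3) added, the trend called 0, 16, 96 and 100% and 1810 unchanged features passed 2-fold. These 2-fold counts were taken over all 22352 features, without the filter and floor used to compare the real arrays. Of 100 random lists without a shift 3 fell outside the central 95%, and all 100 lists shifted by 0.5 did. These lists were simulated with spot error alone, without the spread over features of the real comparisons (standard deviation 0.97 at 0.003%). A shift of 0.5 can therefore be missed there: metal handling at 0.003% had a median of 0.57 and lay inside. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.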

Results

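RNA of NRK-52E cells, a rat kidney tubular epithelial line, was measured 12 h after 1 h in medium with 0, 0.003, 0.006 or 0.009% H2O2. Each of the 4 doses was measured on 1 array, so there were no replicates and each value stands for 1 culture. The series asks which molecules released by injured and dying tubule cells make neighbouring cells divide. Each array held 43379 noncontrol spots. From the control to the highest dose, 53.4, 53.5, 51.8 and 54.9% of the probes were well above background, and no spot was saturated. The 75th percentile of the spot signals was 180, 168, 158 and 121. Values are given as log2 differences from the control array after scaling to this percentile, and the scanner software's spot error had a median of 0.21 and reached at most 0.45 for differences between 2 measured values. Of the reference genes, Gapdh, a glycolytic enzyme, was at 0.08, -0.11 and -0.19 over the 3 doses, its sign at 0.003% turning under quantile normalization, array median and spike-in scaling, which put it at -0.67, -0.75 and -1.37 at 0.009%. Actb, cytoplasmic actin, was at -0.08, 0.12 and 0.28, its sign at the 2 higher doses turning under the same alternatives, to -0.31, -0.28 and -0.90 at 0.009%.

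**Figure D1:**
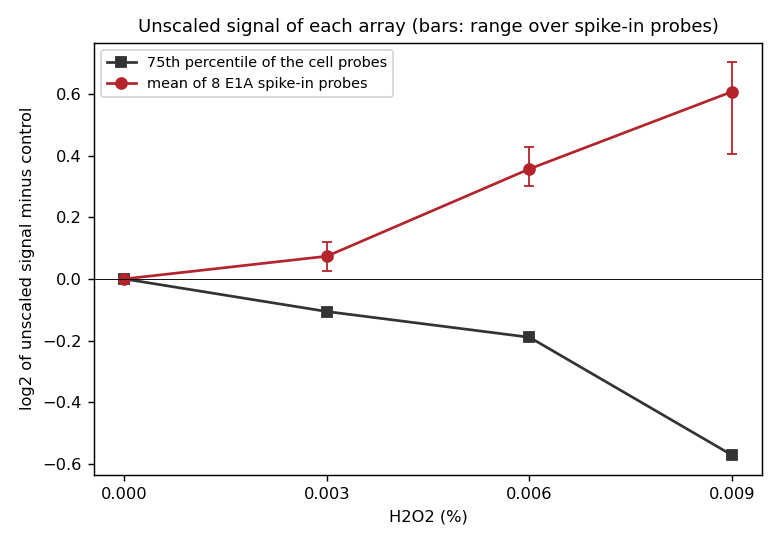
Signals of the 4 arrays by H2O2 dose (%, 1 array per dose): log2 difference from the control array for the 75th percentile of the cell probes and for the mean of 8 probes of the E1A spike-in RNA. The 75th percentile was at -0.57 and the spike-ins were at 0.61 at 0.009%.

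At 0.003% H2O2, the lowest dose, genes of several stress responses were far above the control. Fosl1, a subunit of the AP-1 transcription factor, was 377-fold higher (log2 8.56 ± 0.27, spot error), Ampd1, an AMP deaminase, 53-fold, Hmox1, the haem-degrading enzyme induced by oxidative stress, 47.2-fold, and the inducible heat shock protein gene Hspa1a 43.4-fold. With normexp the differences of Fosl1, Ampd1 and Hspa1a were smaller, at 6.46, 3.69 and 3.57 at 0.003%, and at 5.89, 5.13 and 6.51 at 0.009%. The stress transcription factor Atf3 was 28.6-fold higher, Nppb, which encodes the B-type natriuretic peptide, 27.3-fold, and Trib3 and Ppp1r15a, targets of the integrated stress response, 22.7-fold and 22-fold. Furthest below the control, the collagen-binding integrin Itga1 was at -3.38, Tmem204 at -3.15, the phospholipase Plce1 at -2.90, Megf6 at -2.83, the nuclear receptor Nr0b2 at -2.82, the basement membrane proteoglycan Agrn at -2.81, the adhesion molecule Ncam1 at -2.78 and the protocadherin Pcdha4 at -2.75.

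In all, 3103 features were at least 2-fold higher and 2840 at least 2-fold lower at 0.003%, of 20894 compared. Among these were 917 and 681 of 5680 named genes. The share of the higher among both was 52.2%, and 41.2% with array median or 39.1% with spike-in scaling. Of 28 lists judged, 8 lay outside the central 95% of random lists, against 1.4 by chance: the integrated stress response, immediate early genes, heat shock proteins, p53 targets, ER chaperones and NRF2 targets above, and mitosis and fibroblast markers below.

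At 0.006%, Fosl1 was 438-fold, Hspa1a 158-fold, Ampd1 106-fold and Hmox1 70.7-fold above the control. Atf3 was 42.6-fold, Ppp1r15a 28.7-fold, Zfand2a, which is induced by arsenite and heat, 25.6-fold and Trib3 24.5-fold higher. The lowest genes were Pcdha4 at -2.74, Depp1, a FOXO target, at -2.64, Plce1 at -2.53, Itga1 at -2.44, the septin regulator Cdc42ep2 at -2.42, carboxypeptidase D (Cpd) at -2.40, the NADPH oxidase Duox2 at -2.38 and Tmem204 at -2.33. There were 3072 features at least 2-fold higher and 2165 lower of 20677, with 834 and 453 of 5640 named genes. The higher made up 58.7%, and 34.1% with array median or 19.7% with spike-in scaling. The lists outside the central 95% again numbered 8, against 1.4 by chance. The same 6 stress lists and metal handling lay above, and fibroblast markers below.

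At 0.009%, the highest dose, Hspa1a led with a 371-fold difference (8.54 ± 0.07). Fosl1 was 292-fold, Ampd1 160-fold, Hmox1 68.4-fold, Atf3 52.2-fold, Zfand2a 32.4-fold, the cadherin-related gene Cdhr1 27.7-fold and Ppp1r15a 25.8-fold higher. Depp1 was lowest at -2.88, followed by Cpd at -2.66, the Golgi glycoprotein Glg1 at -2.49, Cdc42ep2 at -2.23, Bbx at -2.17, the homeobox gene Hlx at -2.14, Pcdha4 at -2.07 and Cyp1a1, a target of the aryl hydrocarbon receptor, at -2.07. Of 21459 features, 3536 were at least 2-fold higher and 1587 lower, among them 805 and 300 of 5832 named genes, and 1403 of the higher were bounds. The share of the higher, 69.0%, depended on the scaling: it was 47.7% with quantile normalization, 21.0% with array median and 4.49% with spike-in scaling, and 54.3% with normexp. Outside the central 95% lay 7 lists, against 1.4 by chance: the integrated stress response, immediate early genes, heat shock proteins, p53 targets and ribosomal proteins above, and glycolysis and fibroblast markers below.

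**Figure D2:**
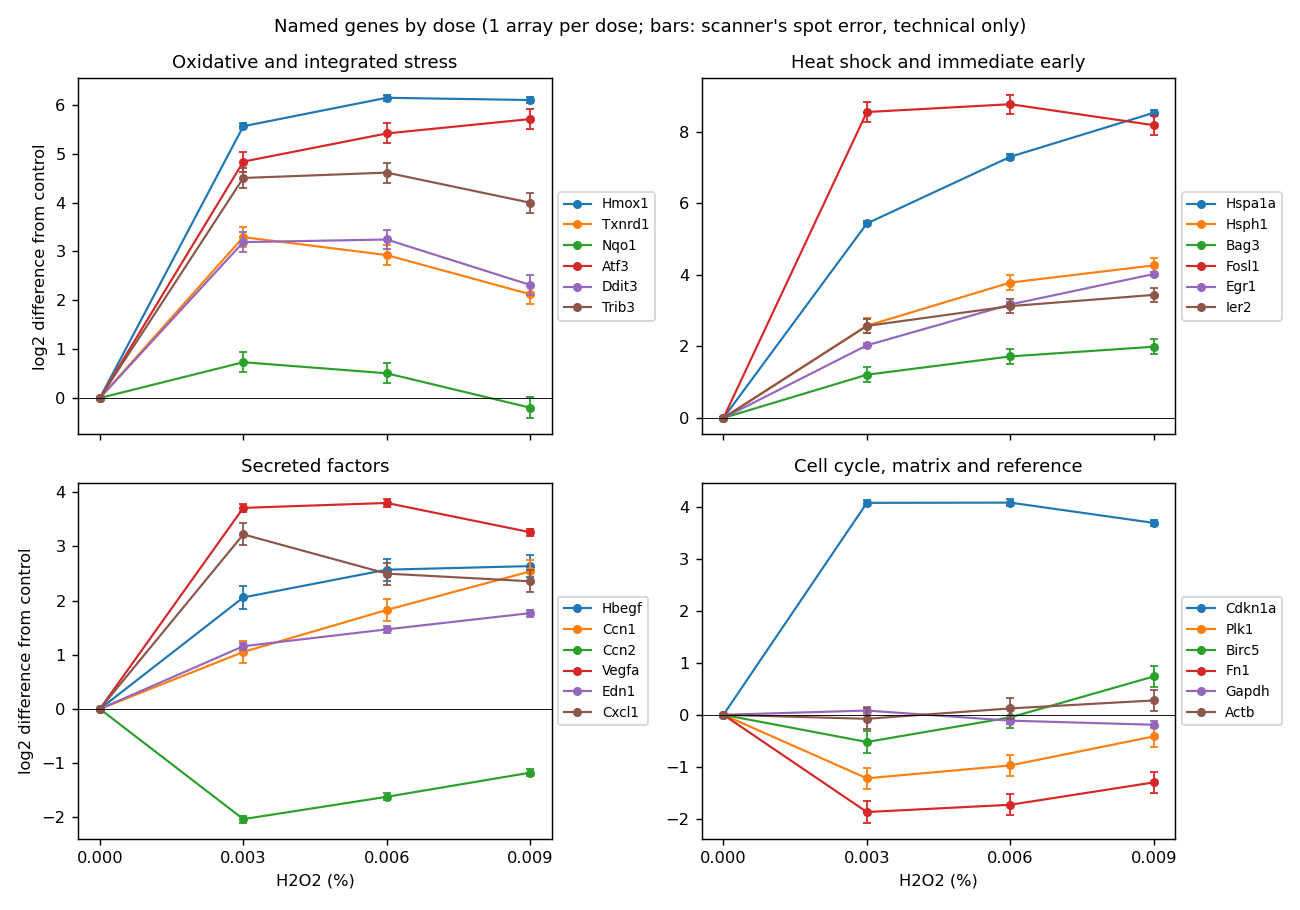
Log2 difference from the control by H2O2 dose (%) for named genes in 4 groups, 1 array per dose, with bars for the scanner software's spot error, which is technical only. Hspa1a was at 5.44, 7.31 and 8.54 over the 3 doses while Txnrd1 was at 3.29, 2.92 and 2.12. Actb at the 2 higher doses, Gapdh at 0.003%, Nqo1 at 0.006% and Birc5 at 0.009% change sign under spike-in scaling.

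Scaling shifted the median of all features by more than 0.1 in several cases, and the group results that follow are relative to the 75th percentile. Array median scaling moved it by -0.15, -0.31 and -0.56 over the 3 doses, spike-in scaling by -0.18, -0.55 and -1.18, and quantile normalization by -0.14 at 0.009%. Array median and spike-in scaling take 1 value from all features of an array, so by construction they hardly move a list among random lists, while signs of medians turned, and a single gene measured at less than 1.18 above the control at 0.009% lies below it with spike-in scaling.

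The integrated stress response, in which phosphorylation of eIF2alpha favours translation of Atf4, had list medians of 2.30, 2.35 and 2.31, the largest of the lists at every dose, although at 0.009% immediate early genes and heat shock proteins were above it with normexp (1.55 and 1.30 against 1.27), and immediate early genes with features well above background on both arrays (2.17 against 1.70). At least 2-fold higher were 17 of 20, 17 of 19 and 15 of 19 measured members, and none was 2-fold lower. Trib3, a pseudokinase that binds Akt, was at 4.50, 4.61 and 4.0, Ddit3, the transcription factor CHOP, at 3.19, 3.24 and 2.31, and the angiogenic factor Vegfa at 3.71, 3.80 and 3.26. ER chaperones and the unfolded protein response had 7, 7 and 4 of 14 members at least 2-fold higher, with medians of 0.97, 0.99 and 0.41, the last becoming -0.16 with array median and -0.78 with spike-in scaling. Dnajb9, an ER co-chaperone, was at 2.86, 3.13 and 2.62, Herpud1, which serves ER-associated degradation, at 2.47, 2.62 and 1.83, and the chaperones Hspa5 and Hsp90b1 were at 1.37 and 1.00 at 0.009%, Hsp90b1 with the opposite sign under spike-in scaling.

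Heat shock proteins, which refold or clear damaged proteins, were at least 2-fold higher in 10, 10 and 11 of 14 members, with medians of 1.18, 1.49 and 1.5. The nucleotide exchange factor Hsph1 was at 2.58, 3.79 and 4.27, the co-chaperone Bag3 at 1.21, 1.72 and 1.99, and the small heat shock protein Hspb8 at 2.66, 2.96 and 2.60. Immediate early genes respond within minutes to growth factors and stress. At 12 h after exposure, the only time measured, 14 of 21, 15 of 19 and 15 of 19 members were at least 2-fold higher. Their medians were 1.29, 1.87 and 2.17. The zinc finger transcription factors Klf4 and Egr1 were at 4.38, 4.24 and 4.06, and at 2.03, 3.17 and 4.03, and Ier2 was at 2.57, 3.13 and 3.44. None of these 2 lists' members was 2-fold lower at any dose.

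Among NRF2 targets, the genes through which cells answer electrophiles and oxidants, 9 of 21 were at least 2-fold higher at 0.003%, 7 of 20 at 0.006% and 4 of 20 at 0.009%. Their median was 0.90, 0.68 and 0.41, the last becoming -0.15 with array median and -0.77 with spike-in scaling. Hmox1 stayed at 5.56, 6.14 and 6.10, and Osgin1, an oxidative stress growth inhibitor, at 4.27, 4.50 and 3.93. Txnrd1, thioredoxin reductase, was at 3.29, 2.92 and 2.12, the quinone reductase Nqo1 at 0.73, 0.51 and -0.20, and the transporter Abcc4 at -0.18, -0.78 and -1.47. The value of Nqo1 at 0.006% was negative with spike-in scaling. Other antioxidant enzymes had medians of 0.08, 0.22 and 0.12, inside the central 95%, and all 3 turned negative with array median or spike-in scaling. Prdx6, Sod1 and Prdx3, which remove peroxides and superoxide, were at 0.89, 0.57 and 0.57 at 0.009%, negative with spike-in scaling and Sod1 also with quantile normalization, and Txnrd2 was at -0.48.

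Targets of p53 were at least 2-fold higher in 7, 7 and 5 of 14 members, with medians of 1.08, 1.09 and 0.51, the last -0.05 with array median and -0.67 with spike-in scaling and inside the central 95%, at the 97.1 percentile, with features well above background on both arrays. Cdkn1a, the cell cycle inhibitor p21, was at 4.09, 4.09 and 3.70. Plk2, a kinase induced by DNA damage, was at 3.38, 3.84 and 3.73, and Gadd45a at 2.78, 3.16 and 2.95. Genes of mitosis had a median of -0.79 at 0.003%, where 3 of 13 were at least 2-fold lower and none higher, -0.38 at 0.006%, and 0.21 at 0.009%, which was -0.36 with array median and -0.98 with spike-in scaling. The mitotic kinase Plk1 was at -1.22, -0.98 and -0.42, Birc5 (survivin) at -0.52, -0.05 and 0.74, and Aurkb at -0.51, 0.37 and 0.77, while Aurka was at 0.39 at 0.009%, these 3 positive values at 0.009% turning negative with spike-in scaling and that of Aurka also with array median scaling. DNA replication genes lay inside the central 95% with medians of -0.22, -0.19 and -0.03. Pcna, the sliding clamp, was at 1.13, 0.92 and 0.65, negative at 0.009% with spike-in scaling, and Rrm1 and Pold1 were at -0.66 and -0.47 at 0.009%. DNA repair genes had medians of -0.42, -0.36 and -0.08. Mutyh was at 0.80 at 0.009%, negative with spike-in scaling, and Brca2 was at least 2.60-fold higher.

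Secreted factors bear on the question of the series. The list of secreted growth factors as a whole lay inside the central 95%, with medians of 0.09, 0.06 and 0.33 that all turned negative with array median or spike-in scaling, the last above the central 95% with normexp, but its members went far in both directions. At 0.003%, 14 of 34 were at least 2-fold higher and 6 lower, at 0.006% 15 and 5 of 34, and at 0.009% 14 and 2 of 35. Gdf15, a stress cytokine also among the p53 targets, was at least 10.0-fold, 13.2-fold and 16.2-fold higher, but at 1.46, 1.71 and 1.93 (log2) with normexp. Of the named genes' differences given as bounds, all 11, 10 and 14 at the 3 doses were nearer to 0 with normexp, as were 104, 105 and 102 of the 122, 122 and 124 measured ones. At 0.009% 12 of these bounds and 86 of the measured differences were at least 2-fold, of which 4 and 62 stayed so with spike-in scaling and 2 and 62 with normexp. Hbegf, a ligand of the EGF receptor, was 4.16-fold, 5.93-fold and 6.21-fold higher, the matricellular protein Ccn1 2.07-fold, 3.54-fold and 5.81-fold, and Vegfa 13.1-fold, 13.9-fold and 9.58-fold. Of the enzymes of prostaglandin synthesis, Ptgs2, the inducible cyclooxygenase, was at least 16.3-fold, 25.2-fold and 21.8-fold higher, but at 1.75, 2.21 and 2.05 (log2) with normexp. The constitutive Ptgs1 was at -1.08, -1.05 and -0.59, the prostaglandin E2 receptor gene Ptger4 was below the control by bounds of -2.39, -1.95 and -1.89 (-0.88, -0.85 and -0.55 with normexp), and Ptgr1, which inactivates prostaglandins and is also an NRF2-responsive gene, was at least 8.82-fold, 6.11-fold and 3.65-fold higher, but at 1.21, 0.98 and 0.86 (log2) with normexp. The list of prostaglandin synthesis and receptors had medians of -0.38, -0.59 and -0.21, with 3 higher and 5 lower of 11 at 0.003%, and lay inside the central 95%.

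Only 3 WNT and hedgehog ligands were measured, too few to judge, with medians of -1.22, -1.09 and -0.91. Wnt4 was at -1.22, -1.35 and -0.91, Wnt5a at 0.63, -0.13 and -0.34, and Shh was below the control by bounds of -1.53, -1.09 and -1.03, but at -0.43, -0.34 and 0.00 with normexp. Damage-associated molecules had medians of -0.05, 0.04 and 0.24, the positive ones turning under quantile normalization, array median and spike-in scaling. Anxa1 was at 0.65 and S100a10 at 0.61 at 0.009%, both negative with spike-in scaling and S100a10 also with quantile normalization, Nampt was at -0.51, and S100a8 was at least 1.92-fold higher, a bound that was lost with spike-in scaling. Inflammatory cytokines and NF-kB targets had 6 of 15, 2 of 13 and 3 of 14 members at least 2-fold higher, and medians of 0.46, -0.25 and -0.24, inside the central 95%. The neutrophil-attracting chemokine Cxcl1 was at 3.22, 2.5 and 2.35, Ccl7 at 1.72, 1.49 and 1.48, Cxcl2 was at least 2.71-fold higher at 0.009%, and Nfkb2 was at -0.42, -0.90 and -0.85. Interferon response genes had medians of 0.02, 0.02 and -0.26, the first 2 turning negative under all 4 alternatives of scaling and background. The chemokine Cxcl10 was at 3.46, 3.60 and 2.61, while Irf9 and Stat2 were at -0.96 and -0.66 at 0.009%.

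Genes of apoptosis and necroptosis had 7 of 31 members at least 2-fold higher and none lower at 0.003%, 6 higher and 2 lower of 30 at 0.006%, and 3 of each at 0.009%. Their medians of 0.39, -0.03 and 0.00 lay inside the central 95%, and the last was -0.56 with array median scaling. Cflar, an inhibitor of caspase-8, was at 2.74, 2.55 and 1.79. The BH3-only gene Hrk was at least 2.91-fold, 3.59-fold and 3.0-fold higher (0.38, 0.59 and 0.66 on the log2 scale with normexp), while Bmf, of the same class, was at 0.26, -1.49 and -1.19 and the initiator caspase Casp9 at -0.84, -1.30 and -1.45. Lysosome and autophagy genes had medians of -0.11, -0.15 and -0.07, inside the central 95%. Gabarapl1, a homologue of yeast Atg8, was at 1.09 at 0.009%, with the opposite sign under spike-in scaling, Atg3 at 0.73, and Atg7 and Neu1 were at -0.94 and -0.76.

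Tubule injury markers had 4 of 16, 6 of 17 and 5 of 17 members at least 2-fold higher and none lower, with medians of 0.17, 0.33 and 0.26 that turned negative with spike-in scaling, the first also with quantile normalization and the last with array median scaling. The keratins Krt18 and Krt19 were at 2.22, 2.76 and 3.1, and at -0.26, 1.01 and 1.64. Cd44, the hyaluronan receptor, was at 3.29, 2.33 and 1.51, and the urokinase receptor Plaur at 1.65, 1.85 and 1.60. Genes of proximal tubule function had 3 of 13 members at least 2-fold lower at 0.003%, and 5 higher and 1 lower of 14 at 0.009%, with medians of -0.41, -0.12 and 0.01, the last -0.54 with array median and -1.16 with spike-in scaling. The water channel Aqp1 was at -2.11, -1.85 and -1.33, the transcription factor Hnf4a at 0.44, 0.87 and 1.25, the glucose transporter Slc5a2 at 0.37, 0.57 and 1.35, and Fbp1 was at least 2.75-fold higher at 0.009%. Epithelial junctions and keratins had medians of -0.09, -0.37 and -0.21. The tight junction protein F11r was at -1.24, -1.16 and -1.09, Cldn3 at 0.79 at 0.009%, and Cldn4 was at least 1.81-fold higher, a bound that was lost with spike-in scaling. Targets of YAP and TGF-beta had medians of -0.12, -0.33 and -0.11, and 2 members at least 2-fold higher and 3 lower at each dose. Ccn1 and the vasoconstrictor gene Edn1 were higher, Edn1 at 1.16, 1.47 and 1.77, and Ccn2 and Id1 were at -2.03, -1.62 and -1.18, and at -1.29, -1.88 and -1.74. These 4 lists lay inside the central 95% at every dose.

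Markers of fibroblasts and mesenchyme had medians of -1.32, -0.97 and -0.53, with 5, 5 and 2 of 10 members at least 2-fold lower, and the last lay inside the central 95% with normexp, at the 4.02 percentile of the random lists. Fibronectin (Fn1) was at -1.88, -1.73 and -1.30, N-cadherin (Cdh2), which kidney tubule cells also express, was below the control by bounds of -2.14 and -1.90 and at -1.16, the transcription factor Snai1 at 0.81, 1.04 and 1.01, the last with the opposite sign under spike-in scaling, and Fap was at least 2.07-fold higher at 0.009%, a bound that was lost with spike-in scaling. With normexp Cdh2 was at -0.62, -0.49 and -0.15. Of the endothelial markers 2, 2 and 3 were measured, too few to judge. The receptor genes Kdr and Eng were at 0.92, 1.2 and 1.59, and at 1.67, 1.57 and 1.21, and Plvap was at least 2.18-fold higher at 0.009%, a bound that was lost with spike-in scaling. Macrophage and leukocyte markers lay inside the central 95% with medians of 0.26, -0.05 and 0.88, the last -0.30 with spike-in scaling. Tyrobp was at 1.10 at 0.009%, with the opposite sign under spike-in scaling, Aif1 at 0.93, Cd14 at -1.06, and C1qc was at least 2.07-fold higher, which was lost with spike-in scaling.

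Glycolysis and hypoxia response genes had medians of 0.00, -0.30 and -0.43, the first turning negative under the 4 alternatives of scaling and background and the last below all but 0.04% of the random lists, with 2 of 19 members at least 2-fold higher and 4 lower at the 2 higher doses. Lactate dehydrogenase (Ldha) was at -0.39, -0.96 and -1.13, phosphofructokinase (Pfkl) at -0.80, -1.31 and -1.19, the mitophagy receptor gene Bnip3 at -0.61, -1.05 and -1.25, and hexokinase 2 (Hk2) at 2.65, 2.59 and 1.49. None of 33 cytosolic ribosomal protein genes was 2-fold higher or lower, and their medians of 0.32, 0.48 and 0.69 turned negative with spike-in scaling at the 2 higher doses (-0.07 and -0.49). Rps23, Rpl14, Rpl11 and Rpl30 were at 0.99, 0.96, 0.90 and 0.88 at 0.009%, all negative with spike-in scaling. The ribosomal median lay above the central 95% at 0.009% but inside it with quantile normalization, at the 97.1 percentile of the random lists. Oxidative phosphorylation had medians of -0.24, -0.11 and 0.01, the last negative under those 4 alternatives. Cytochrome c (Cycs) was at 1.26, 1.08 and 0.65, the last negative with spike-in scaling, Cox5a at 0.56, and Atp5f1a and Ndufs1 at -0.74 and -0.63 at 0.009%. Cholesterol synthesis had medians of -0.45, -0.34 and -0.08, with Idi1, Msmo1 and Insig1 at 1.47, 1.09 and 1.04 at 0.009%, the last 2 negative with spike-in scaling, and squalene synthase (Fdft1) at -1.06. Metal handling had medians of 0.57, 0.67 and 0.06, the last negative with quantile normalization, array median and spike-in scaling. Its place above the central 95% at 0.006% was lost in several alternatives, to the 70.4 percentile with the mean of a gene's probes. The zinc exporter Slc30a1 was at 2.31, 2.49 and 1.94, ferritin light chain (Ftl1) at 1.2, 1.24 and 1.33, the iron importer Slc11a2 at -1.28, -1.67 and -1.61 and the copper transporter Atp7a at -0.29, -0.66 and -1.18.

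**Figure D3:**
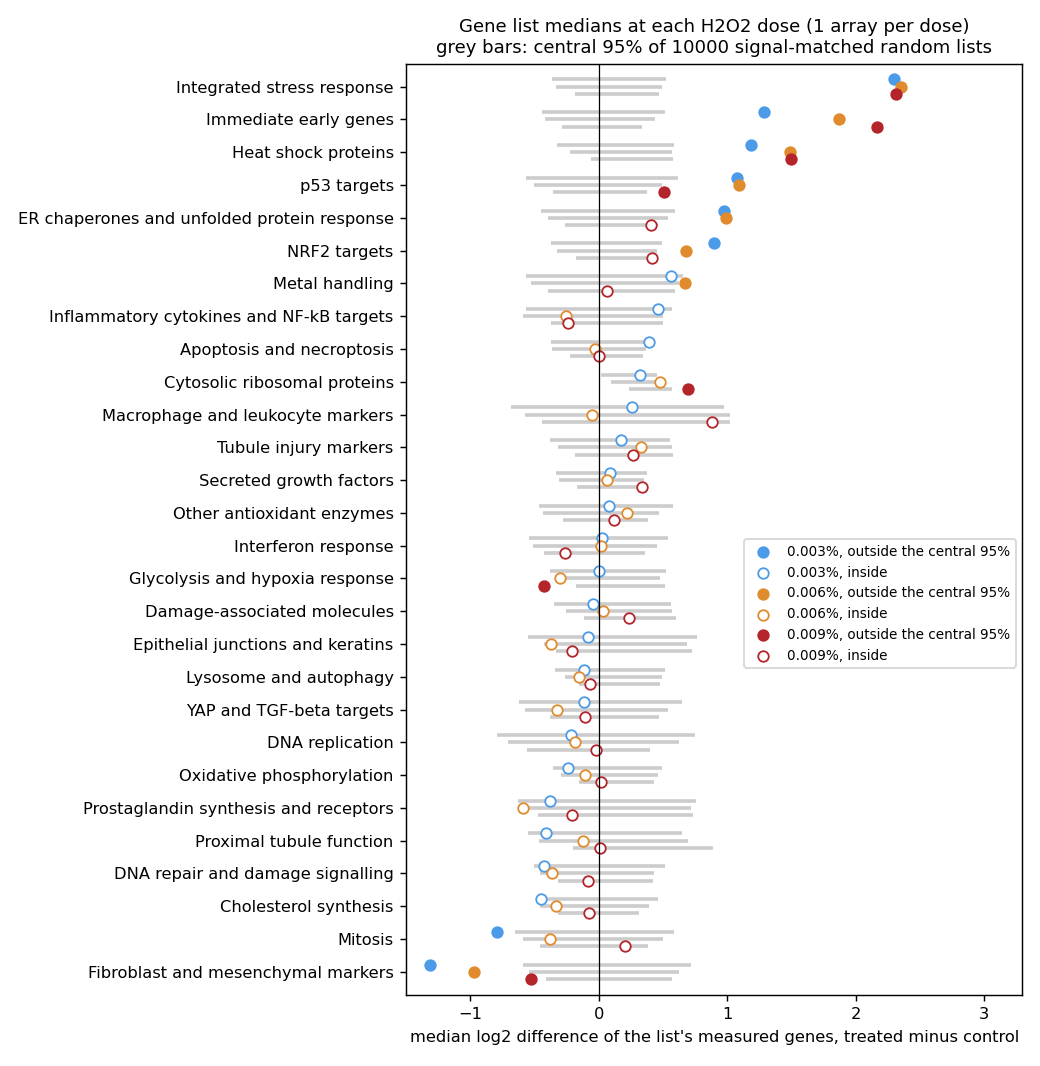
Median log2 difference from the control of the measured genes of the 28 lists judged, at each H2O2 dose (1 array per dose), with grey bars for the central 95% of 10000 random lists matched on signal and filled points outside it. Integrated stress response medians were 2.30, 2.35 and 2.31 and fibroblast marker medians -1.32, -0.97 and -0.53, while 5, 6 and 14 of all 30 list medians changed sign under spike-in scaling at the 3 doses.

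Between neighbouring doses several lists moved in opposite directions. Heat shock proteins and immediate early genes were higher at 0.006% than at 0.003%, with list medians of 0.35 and 0.22 above the central 95%, as were secreted growth factors at 0.21 and mitosis at 0.38, which were -0.02, -0.15, -0.16 and 0.01 with spike-in scaling. NRF2 targets (-0.13), inflammatory cytokines (-0.48), apoptosis (-0.22) and glycolysis (-0.33) lay below. From 0.006% to 0.009%, mitosis (0.50) and fibroblast markers (0.43) lay above, at -0.14 and -0.20 with spike-in scaling, and NRF2 targets (-0.25), the integrated stress response (-0.39), ER chaperones (-0.52), apoptosis (-0.15), glycolysis (-0.14) and the interferon response (-0.28) below. Of 20095 features, 470 were at least 2-fold higher and 211 lower at 0.006% than at 0.003%, and of 20664, 403 and 260 at 0.009% than at 0.006%. With spike-in scaling these counts were 141 and 861, and 41 and 3244. The share of the higher was 69.0% in the first of these steps (53.2% with quantile normalization, 40.5% with array median and 14.1% with spike-in scaling) and 60.8% in the second (35.2, 16.7 and 1.25%, and 40.5% with normexp).

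Over the whole series, genes split into those whose difference from the control was kept or grew with the dose and those for which it shrank. Hspa1a, Egr1 and Ccn1 were highest at 0.009%, and Cyp1a1, Depp1 and Cpd lowest there. Cd44, Txnrd1, Cxcl1 and Hk2 were highest at 0.003%, and Itga1, Tmem204, Megf6 and Nr0b2 lowest there. These orders were the same with quantile normalization, array median and spike-in scaling, while with normexp Cyp1a1 was lowest at 0.006% (-1.13, against -1.06 at 0.009%). At 0.003%, 2372 features well above background on all arrays were at least 2-fold higher. Of these, 1134 differed at least 2-fold from the control at 0.009%, in either direction. The median of the 2372 was 1.45, 1.35 and 0.95 over the doses. The 2296 features at least 2-fold lower had medians of -1.40, -1.21 and -0.84. Of these, 897 differed at least 2-fold from the control at 0.009%, again in either direction. This return of the lower features depended on the scaling: at 0.009% the medians of the higher and the lower features were 0.39 and -1.40 with array median and -0.23 and -2.02 with spike-in scaling. Features chosen for their value on the 0.003% array are partly chosen for its chance deviations. The 2027 features at least 2-fold higher at 0.009% had medians of 1.14, 1.40 and 1.38 over the doses, 663 of them being lower at 0.009% than at 0.003%, and the 1333 at least 2-fold lower there had medians of -1.35, -1.45 and -1.28. With spike-in scaling the medians of these features at 0.003% and 0.009% were 0.96 and 0.20, and -1.53 and -2.46. A comparison of 0.009% with 0.003%, added after this had been seen, put 10 of 28 lists outside the central 95%, against 1.4 by chance: heat shock proteins (0.48), mitosis (0.88, with 13 of 13 members higher), proximal tubule function (0.83) and fibroblast markers (0.94) above, and NRF2 targets (-0.40), the integrated stress response (-0.35), ER chaperones (-0.32), inflammatory cytokines (-0.40), apoptosis (-0.52) and glycolysis (-0.38) below. With spike-in scaling the first 4 medians were -0.52, -0.12, -0.17 and -0.06, and 4 of the 13 mitosis genes were higher. Proximal tubule function lay inside the central 95% with spike-in scaling and without filter, inflammatory cytokines with quantile normalization and with the mean of a gene's probes, and ER chaperones with normexp.

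**Figure D4:**
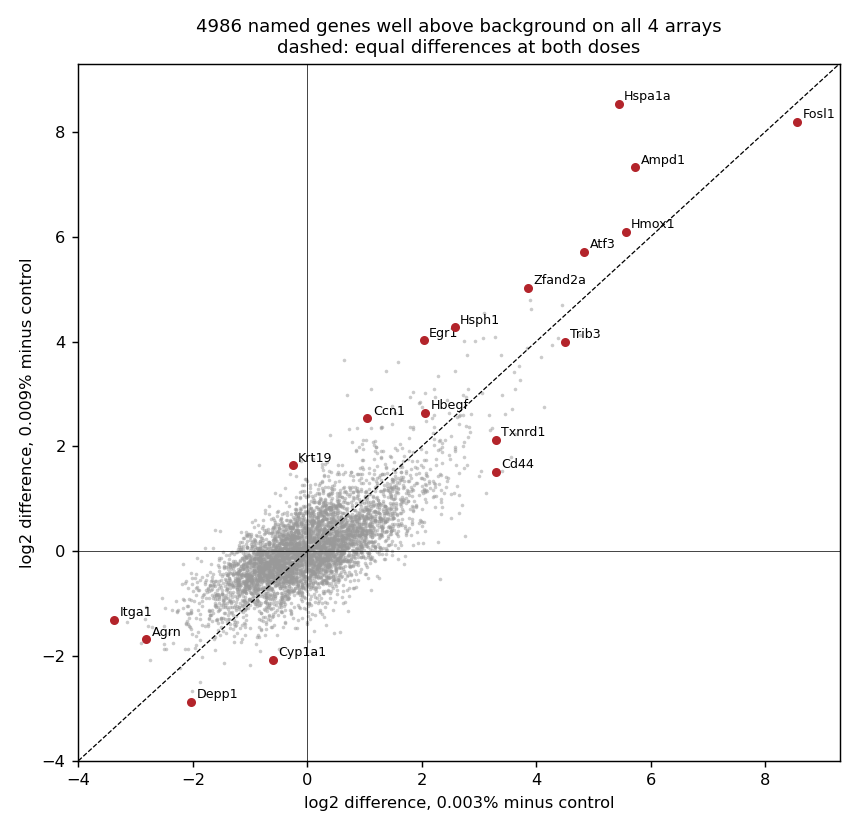
Log2 difference from the control at 0.009% against that at 0.003% H2O2 for 4986 named genes well above background on all 4 arrays (1 array per dose), with named genes in red and the dashed line at equal differences. Of these genes 3200 were further from 0 at 0.003%.

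No feature passed the test of a straight-line trend over dose (limma, Benjamini-Hochberg, 4 arrays, 22352 features, smallest adjusted p 0.258). At an unadjusted p under 0.05 there were 3095 features, 2487 higher and 608 lower with dose, a split that depended on the scaling and the filter. It was 1506 and 1146 with quantile normalization, 1094 and 2619 with array median and 424 and 7426 with spike-in scaling. With features well above background on every array it was 1353 and 604, and without filter or floor 6481 and 922. Without the 0.003% array limma called 330 features (321 higher, 9 lower, smallest adjusted p 0.0430 after Benjamini-Hochberg), and without the control, the 0.006% or the 0.009% array none. Adjusted over the list alone, limma with Benjamini-Hochberg called 4 heat shock genes (Bag3, Hspa1a, Hspe1 and Hsph1), against 0 over all features. Called in the same way were 3 immediate early genes (Egr1, Fos and Jun). So was 1 gene in each of the lists of YAP and TGF-beta targets (Ccn1), endothelial markers (Kdr) and macrophage markers (C1qc). Each list was adjusted by itself, with no correction over the lists. The endothelial list had 3 tested members, too few to judge. C1qc had a difference from the control at 0.009% only, a bound that was lost with spike-in scaling. All these calls were made with the main scaling and were not repeated with the others. With spike-in scaling Bag3 was at 1.03, 1.17 and 0.81 over the doses, and Kdr at 0.74, 0.65 and 0.41. Hsph1 was then highest at 0.006%, while Hspa1a, Egr1 and Ccn1 stayed highest at 0.009%. Hspe1, Fos and Jun are named here after their values were seen. With the control against the 3 treated arrays as a group, limma called none after Benjamini-Hochberg (smallest adjusted p 0.0521, 5496 features at an unadjusted p under 0.05).

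Across features the differences from the control at different doses went together. Pearson's r was 0.919 (Spearman's rho 0.903) between 0.003% and 0.006%, 0.734 (0.689) between 0.003% and 0.009%, and 0.896 (0.868) between 0.006% and 0.009%, over 20064 features, which are not independent replicates. These comparisons share the control array, which alone gave r of 0.490, 0.493 and 0.484 in simulated unchanged arrays. A shared control gives such an r whatever the size of the noise, so it is no baseline for the observed r. The observed covariances were 0.884, 0.667 and 0.777 over the 20064 features, against 0.026 in each simulated pair. The simulated arrays held only features well above background on every array. Over those 17053 features the observed covariances were 0.842, 0.610 and 0.709. The simulated arrays hold spot error only, so a deviation of the control culture itself is not covered. The change from the control to 0.003% and the change from 0.006% to 0.009%, which share no array, were negatively related (r -0.567, rho -0.576, 17053 features). Features at least 2-fold different at 0.003% were also looked up in the comparisons at the other doses, bounds included. Of the higher ones, 2247 were 2-fold higher at 0.006% and 1507 at 0.009%, against 414 and 396 if the doses were independent. Of the lower ones, 1816 and 1102 were 2-fold lower, against 304 and 223. Opposite 2-fold differences were seen in 3 and 7 features. Spot error alone, with a shared control, gave on average 0.41 and 0.23 shared higher features in simulated unchanged arrays. These held fewer and brighter features, without bounds, so the simulated counts are no direct baseline for the 2247 and 1507.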

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

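All tests of explanations in this part were chosen after the results they concern had been seen.

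With 1 array per dose, no array could be set against others of its dose. The spike-in RNA, which is outside the main measurement, stood out because its signal was above that of the control array: by 0.61 on the log2 scale at 0.009% (8 probes of E1A, 0.41 to 0.70 between probes) and by 0.36 at 0.006% (0.30 to 0.43). At 0.003% it was at 0.07.

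The first pattern weighed is that spike-in signals were higher while cell signals were lower at 0.009%. A brighter hybridisation or scan of the whole array together with less cell RNA was not tested. A few genes taking most of the signal was tested on the 100 brightest probes and does not account for the whole of it. These probes held 20.8% of the summed signal in the control and 26.0% at 0.009%. At a constant summed signal this would lower the other probes by -0.098, against -0.57 for the 75th percentile. The summed signal itself was lower at 0.009% (3.12e+07 against 3.58e+07 in the control), and a shift over more probes was not tested. Less cell RNA per unit of spike-in may account for it, but the test cannot decide. Against the spike-ins cell signals were lower in all 10 bins of signal, which restates the pattern, by medians from -0.71 to -1.34. About the same lowering at every brightness had been predicted from this cause, and the medians differed between bins. Only opposite directions between bins were to count against it. Less cell RNA cannot be told apart from an effect of array position, which followed the dose. The amounts of RNA labelled are not given in the sources used here. A lower RNA yield of the injured cells stays open as a biological explanation and was not tested.

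The second pattern is that many differences from the control were smaller at 0.009% than at 0.003%. For the features at least 2-fold higher at 0.003%, the median was lower at 0.009% by at least -0.49 under each of 4 scalings. Array median and spike-in scaling lower every feature further at 0.009% than at 0.003%, so their larger falls were fixed in advance. With the main scaling the median went from 1.45 to 0.95, and with quantile normalization from 1.38 to 0.85. No scaling tried removed the fall, but the right scaling is not known and the features were chosen on the 0.003% array. For those 2-fold lower, array scaling also stays open. With spike-in scaling their median went from -1.58 to -2.02, further from the control (a change of -0.44). A chance deviation of a single array, such as a culture that responded less, could give this pattern: the first and the last dose step share no array and were negatively related across features (r -0.567, and -0.735 to -0.276 within 10 bins of signal), outside simulated unchanged arrays (-0.0195 to 0.0201), but these hold spot error only and 1 array per dose leaves the spread between cultures unknown. A larger share of cells or RNA that stayed at the control state could also account for part of it, and the test cannot decide. Of the features at least 2-fold higher at 0.003%, 11% were higher still at 0.009% beyond their spot error, but only 2.11% with spike-in scaling. Such rises would count against this share only if the other cells responded alike at both doses, which is not known. Choosing features on the 0.003% array favours such a return by itself: the features at least 2-fold higher at 0.009% had a median of 1.14 at 0.003% and of 1.38 at 0.009%, but of 0.96 and 0.20 with spike-in scaling.

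The third pattern is that more features followed the dose at an unadjusted p under 0.05 (3095) than in most other orders of the arrays. The count was as large in 2 of the 12 orders, the real one included, and the highest other was 4969, with the control followed by 0.009%, 0.006% and 0.003%. The 12 orders are too few for a share under 0.05.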

How the results depend on the processing

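The comparison of 0.009% with 0.003% with its alternatives, and the alternatives for neighbouring doses other than quantile normalization and the deposited table, were chosen after the data had been seen, and the others before. The counts of lists outside the central 95% stayed between 8 and 11 at 0.003%, 7 and 10 at 0.006% and 7 and 8 at 0.009% under the 8 alternatives, of which array median scaling, the deposited table and spike-in scaling take about 1 value from all features of an array and by construction hardly move a list among random lists. The counts of 2-fold differences moved with the scaling, which for these 3 alternatives follows from that shift, while quantile normalization also changes the spread. At 0.006% the higher numbered 1955 with array median scaling and with the deposited table and 1342 with spike-in scaling, and the lower 3782, 3782 and 5483. At 0.009% the higher numbered 2129 with quantile normalization, 1287 with array median scaling, 1288 with the deposited table and 513 with spike-in scaling, and the lower 4843, 4843 and 10911. Between 0.006% and 0.003% the higher numbered 310 with quantile normalization, 265 with array median scaling and the deposited table, 141 with spike-in scaling, 25 with normexp, 239 with features well above background on both arrays and 2544 without filter, and the lower 390 with array median scaling and the deposited table, 861 with spike-in scaling, 12 with normexp, 117 with features well above background on both arrays and 724 without filter. Between 0.009% and 0.006% the higher numbered 156 with array median scaling and the deposited table, 41 with spike-in scaling, 15 with normexp, 208 with features well above background on both arrays and 2759 without filter, and the lower 549 with quantile normalization, 779 with array median scaling and the deposited table, 3244 with spike-in scaling, 22 with normexp, 172 with features well above background on both arrays and 755 without filter. Normexp, whose offset compresses dim signals, gave 1383, 1214 and 906 higher and 1303, 1048 and 762 lower at the 3 doses, and moved 129 of 403 differences of named genes by more than their spot error. Without filter and floor 4827, 6011 and 8525 were higher, and with features well above background on every array compared 2133 were higher at 0.009%. Without filter the correlations were 0.818, 0.638, 0.824 and, for the first and last steps, -0.264, and the cause was not tested. Of the genes named by the rule, 6 that were 2-fold higher at 0.009% changed sign with spike-in scaling: Gabarapl1 (-0.086), Hsp90b1 (-0.18), Insig1 (-0.15), Msmo1 (-0.10), Snai1 (-0.18) and Tyrobp (-0.079). The dose trend called 330 features without the 0.003% array and 0 in every other alternative, and with 1 array per dose the left-out fits rest on 1 residual degree of freedom and a spread pooled over genes. On each array 51.8 to 54.9% of the probes were well above background, and a feature below that on 1 side of a comparison gave a bound only.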

Other observations

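The genes named in this part, and the comparisons by feature class and by control signal, were chosen after their values had been seen, and no explanation was tested.

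Further members of the list of secreted growth factors went in both directions. Among ligands of the EGF receptor family, Areg was 2.57-fold, 3.3-fold and 3.16-fold higher over the 3 doses, Ereg was at least 3.89-fold, 3.46-fold and 2.26-fold higher (the last bound lost with spike-in scaling), and Nrg1 was 4.65-fold, 3.84-fold and 2.07-fold higher (at 0.009% lower than the control with spike-in scaling), while Tgfa was at 0.32, -0.79 and -1.41. The insulin-like growth factor gene Igf2 was 2.5-fold, 2.91-fold and 3.75-fold higher. Fgf21, a hormone of the integrated stress response, was at least 4.33-fold, 5.10-fold and 5.68-fold higher, and the vasodilator gene Adm at least 3.87-fold, 4.94-fold and 4.94-fold. With normexp Ereg, Fgf21 and Adm were at 0.64, 1.02 and 0.94 (log2) at 0.009%. Tgfb3 was at -2.03, -1.55 and -0.94, Fgf18 at -2.04, -1.18 and -0.42, Gas6, a ligand of the TAM receptors, at -1.71, -1.14 and -0.67, and Tgfb1 at -1.08, -1.08 and -0.67.

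The chemokine genes Ccl20 and Ccl2 were at 2.33, -0.27 and -0.53, and at 1.70, 0.18 and -0.24 over the 3 doses, the values of Ccl20 at the 2 higher doses turning positive with normexp and that of Ccl2 at 0.006% negative with array median and spike-in scaling. Myc, a driver of cell growth, was 6.63-fold, 8.33-fold and 7.89-fold higher. Of the integrated stress response, asparagine synthetase (Asns) was at 2.65, 2.18 and 1.08, the last negative with spike-in scaling, and Slc3a2, a subunit of amino acid transporters, at 3.17, 3.29 and 2.60.

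At 0.009% the median difference was 0.45 for 540 features known by a probe ID only, 0.22 for 3823 expressed sequence tags or mRNA accessions, -0.14 for 1432 cluster consensus sequences, 0.11 for 2525 other RefSeq models, 0.066 for 3747 Ensembl transcripts and 0.00 for 4986 named genes, all well above background on every array. By signal on the control array, the dimmest of 10 groups of features had medians of 0.40, 0.61 and 0.82 over the doses and the brightest 0.08, 0.05 and 0.16, in groups chosen by the same control values that enter the differences. Repeated spots of 263 probes, 10 each, had median standard deviations of 0.0794, 0.0781, 0.0734 and 0.0784 on the log2 scale. Of 1029 genes with several measured probes, 73 had probes whose differences at 0.009% were more than 2-fold apart, and 2 had probes with opposite 2-fold differences.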
